A study of Mus musculus with 8 samples.

How the data were processed

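The series holds 8 single-colour Affymetrix arrays of mouse ankle joint, taken at 5 months of age. Per the labels' protocols, total RNA was extracted with TRIzol, purified on columns and amplified into biotin-labelled cRNA. The labels place 2 arrays in a wild-type group, 3 in a group carrying a human TNF transgene with normal sphingosine kinase 1 (hTNF) and 3 in a group carrying the transgene and labelled functionally null for sphingosine kinase 1 (Sphk1). Each label speaks of 1 mouse, but nothing says that the arrays of a group came from separate litters or preparations. The p-values therefore measure only the spread between these arrays, which may be technical in part. Xist and Y-linked levels differed between arrays of each group, so the arrays of a group did not all hold the same RNA.

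The authors deposited 1 table of log2 expression values with 45101 probe sets, rounded to 2 decimals. Per the submitters' processing notes, Affymetrix Expression Console, RMA and MAS5 were used; which of them made the deposited values, and in which version, is not given in the sources used here. The array medians lie between 6.84 and 6.89 log2, so the values carry no information on differences in total RNA between groups. Summary values of this kind also compress changes of very bright and very dim probe sets, so a fold change is a fold of summarised brightness. For arrays, the number of arrays limits the precision: with 2 to 3 per group, the median standard error of a log2 difference was 0.15 between hTNF and wild type and 0.13 between the 2 transgenic groups.

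Probe sets were named from the platform annotation, with symbols updated through the gene identifier in a GRCm38.p6 gene table. Of all probe sets, 34945 had 1 gene, 932 had several and 9160 had none listed, and 64 were control probe sets. The gene of 34741 probe sets matched the gene table. Unnamed probe sets and those of several genes were tested and counted, not named. No genome build is given for the array values, so no coordinates are printed and the GRCm38.p6 table served only for names, for the chromosome of a gene and for which genes neighbour each other. Genes of the lists that the annotation does not name are not analysed here.

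Control probe sets were left out, and a probe set was kept where its value exceeded the median of the whole table (6.87) on at least 2 of the 8 arrays, without regard to group, which left 24115 probe sets. A model with 1 mean per group was fitted to all 8 arrays with limma 3.58.1 (R 4.3.3), with moderated variances and an intensity trend, because the wild-type group has only 2 arrays; this leaves 5 residual degrees of freedom. The 3 contrasts were hTNF against wild type, hTNF labelled Sphk1 null against hTNF, and hTNF labelled Sphk1 null against wild type. Adjusted p is the Benjamini-Hochberg value over all tested probe sets of a contrast, and a probe set was called at an adjusted p under 0.05. "Rose" and "fell" are used only for called probe sets. A gene was represented by its brightest tested probe set assigned to that gene alone, which gave 12362 genes.

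The fit was tested on simulated data with 200 changed probe sets among 24115 in 5 runs. For hTNF against wild type it recovered 15.5% of changes of 0.5 log2, 81.2% of changes of 1 log2 and 98.5% of changes of 2 log2, with 6.2 false calls on average. For the 2 transgenic groups it recovered 18.2%, 84.5% and 99.1% of the same sizes, with 9.2 false calls. The simulated transgenic groups gave 143.4 calls on average and the real ones 2. With fewer calls the adjusted threshold demands a smaller p, so these shares overstate what the real contrast could recover. Noise was drawn separately for each probe set. Differences between arrays that run through many probe sets are therefore not covered by these shares and false calls.

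Of 32 gene lists fixed before the data were examined, 30 had at least 5 measured genes and were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists; the sex-linked list served only as a check and the mast cell list had too few measured genes. Camera asks whether a list ranks higher or lower than the other genes. It was repeated with a correlation estimated for each list, and fry, which asks whether the genes of a list move one way on balance, was run beside it. With the estimated correlation no list passed in any contrast. Genes of a list were counted as called over all probe sets and, in a second count, adjusted over the list alone.

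The genes named were set by a rule written before the data were examined. For each of the first 2 contrasts it takes the 8 largest rises and 8 largest falls among called genes whose groups do not overlap, filled up to 5 by the smallest unadjusted p where too few passed. For the third contrast it takes the 4 largest each way. It adds up to 4 members of each list with the largest called change, or the smallest p where none was called, and a fixed set of genes of sphingosine, cytokine, prostaglandin and bone-resorption biology whatever their value, of which Il6 and Ptgs2 were too dim to be tested. Genes beside Sphk1 were chosen after the values were seen.

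To ask whether the transgene response was smaller in the arrays labelled Sphk1 null, each hTNF array was held out in turn: called probe sets were taken from the other hTNF arrays and wild type, and the median difference between the arrays labelled null and the held-out array was taken over them. The contrasts share the hTNF arrays with opposite sign, so their correlation and covariance are given beside those of 100 simulated data sets with no change. Alternatives covered the dim filter, quantile normalization, median centring, an offset of 32 on the linear scale before log2, the variance model, array weights, 1 probe set per gene, only the 2 groups compared, the replicate number as a block, other list tests and leaving out each array. Y-linked signal (present or not) as a covariate, leaving out X and Y genes and leaving out the 3 arrays with both Xist and Y-linked signal were added after seeing the data.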

Results

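Gene expression was measured in whole ankle joints of 5-month-old mice on 8 arrays: 2 from wild-type animals, 3 from mice with a human TNF transgene (hTNF), which is used as a model of inflammatory arthritis, and 3 from hTNF mice labelled null for Sphk1. Sphk1 is the kinase that makes sphingosine 1-phosphate. The design sets the transgenic joints against wild type and asks whether loss of Sphk1 alters the transgenic joint. Across the 24115 tested probe sets, arrays of 1 group correlated at 0.962 to 0.985, wild-type with transgenic arrays at 0.862 to 0.916, and the 2 transgenic groups with each other at 0.950 to 0.990. The first principal component held 66.7% of the variance and separated wild type from all transgenic arrays.

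Arrays of 1 group differed in the level of some cell type markers. The mean level of 23 skin and keratinocyte genes ranged within the hTNF group from 6.44 to 11.13 log2 and within the arrays labelled Sphk1 null from 6.62 to 9.64. The 19 neutrophil and granulocyte precursor genes averaged 7.44 on wild-type replicate 1 and 9.79 on wild-type replicate 2, and the 28 proliferation genes 7.24 and 8.31. The arrays also differed in sex-linked transcripts. Xist, expressed from the inactive X chromosome, was low on wild-type replicate 1 (7.45) and hTNF replicate 2 (7.29), which had Y-linked Eif2s3y at 8.86 and 8.75. The array labelled Sphk1 null, replicate 1, had both Xist at 11.19 and Eif2s3y at 9.14. Wild-type replicate 2 and hTNF replicate 1 had Xist above 13 and Eif2s3y at 6.91 and 6.60, against 3.46 to 3.81 on the remaining 3 arrays.

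Sphk1, the targeted gene, was highest in the arrays labelled Sphk1 null. Its tested probe set read 7.25 and 7.16 log2 in wild type, 8.63, 8.65 and 8.28 in hTNF, and 9.94 to 10.22 in the 3 arrays labelled null. It rose by 1.32 ± 0.15 log2 (SE, 3 arrays against 2; limma adjusted p = 0.000234) in hTNF against wild type, and by a further 1.53 ± 0.13 (2.89-fold, 3 against 3; limma adjusted p = 0.0164) in the arrays labelled null against hTNF. The level gives no evidence for the null label, and every direction below that rests on this label carries that limit. The labels call the animals functionally null, and the position of the probe set relative to the inactivated part of the gene is not given, so a transcript without function is not excluded and the level does not check the label. A second Sphk1 probe set, too dim to pass the filter, read 6.12 to 6.74 on all 8 arrays and did not follow the first: its difference between the arrays labelled null and hTNF was -0.11 log2 (limma adjusted p = 0.904 without the filter).

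**Figure D1:**
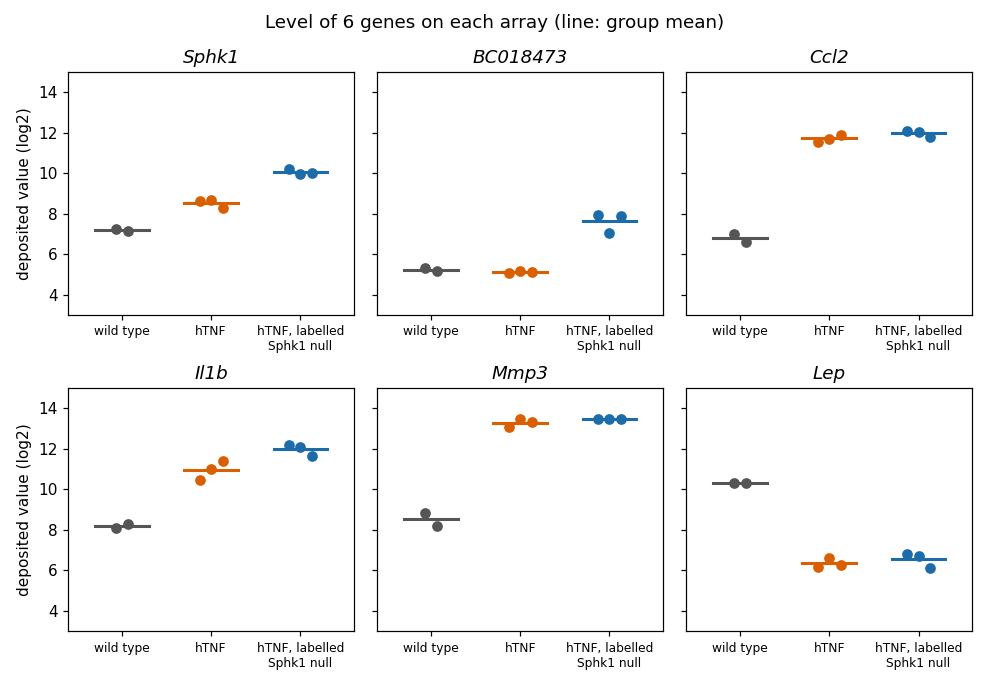
Deposited log2 value of 6 genes on each of the 8 arrays, with points for single arrays and a line for each group's mean. Sphk1 lies between 9.94 and 10.22 on the arrays labelled Sphk1 null and between 8.28 and 8.65 on the hTNF arrays, and BC018473 is raised only on the arrays labelled null, while Ccl2 and Mmp3 are high and Lep is low on both transgenic groups.

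Joints of hTNF mice differed widely from wild-type joints, with inflammatory genes higher and muscle and fat genes lower. The largest rises were in Clec4e (6.40 ± 0.23 log2), a macrophage receptor of the C-type lectin family, the chemokine Cxcl3 (5.94 ± 0.26), the acute-phase protein Saa3 (5.65 ± 0.26), the B-cell-attracting chemokine Cxcl13 (5.49 ± 0.36). They were followed by the monocyte chemokine Ccl2 (4.91 ± 0.15), Clec4d (4.79 ± 0.22), the matrix protease Mmp3 (4.77 ± 0.17) and the arginase Arg1 (4.67 ± 1.25). Clec4e, Cxcl3, Cxcl13, Ccl2 and Arg1 averaged below the value of the dim filter in wild type, so the size and order of these rises depend on the background. With an offset of 32 before log2, Clec4e was at 5.86, Cxcl3 at 4.17 and Arg1 at 3.89. All errors are standard errors over 3 arrays against 2, and the limma adjusted p of these genes was at most 1.86e-05 except for Arg1 (0.0181), whose call ended without either wild-type array (adjusted p = 0.112 and 0.0586). The largest falls were in the adipokine Lep (-3.96 ± 0.22), the fast myosin Myh4 (-3.28 ± 0.36), Ppp1r27 (-3.01 ± 0.23), Nnat (-2.85 ± 0.42), Tmem45b (-2.81 ± 0.23). Next came the slow-muscle myosin light chain Myl3 (-2.78 ± 0.25), Thrsp (-2.78 ± 0.25), which promotes lipid synthesis, and the muscle protein Myom2 (-2.70 ± 0.23). In all, 7965 probe sets were called by limma (33.0% of 24115), 4013 higher and 3952 lower, and 2412 of them by at least 2-fold (1212 higher, 1200 lower). The groups did not overlap in 61.5% of probe sets, against 20% by chance. Leaving out wild-type replicate 1 reduced the count to 4695. The actin control signal, 3' minus 5' end, was 0.47 to 0.60 log2 on the hTNF arrays and 0.37 and 0.45 in wild type.

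Genes of inflammatory signalling rose together in hTNF joints. Of 21 measured genes of the TNF and NF-kB response, 19 rose and none fell (20 and 0 adjusted over the list alone), led by Saa3, the NF-kB inhibitor Nfkbie (3.15 ± 0.21), the adhesion molecule Icam1 (2.56 ± 0.16) and Traf1 (2.54 ± 0.24). Of 23 chemokines, 18 rose and 1 fell (18 and 1 adjusted over the list alone), with the neutrophil chemokine Cxcl5 (4.62 ± 0.21) beside Cxcl3, Cxcl13 and Ccl2. The camera adjusted p was 1.67e-12 and 7.16e-10 for these 2 lists, and the adjusted p = 0.168 and 0.154 with an estimated correlation. Of 20 inflammatory cytokines and receptors, 13 rose and 1 fell (15 and 1 adjusted over the list alone; camera adjusted p = 5.09e-06, adjusted p = 0.162 with an estimated correlation). Il1b rose by 2.75 ± 0.25, the interleukin 1 antagonist Il1rn by 2.69 ± 0.16, mouse Tnf by 1.22 ± 0.14 and Il18 by 1.15 ± 0.15, while Il17a differed by -0.01 ± 0.13 (limma adjusted p = 0.951). In JAK-STAT feedback, 8 of 16 genes rose and none fell (10 and 0 adjusted over the list alone), among them Socs3 (1.28 ± 0.18), Jak2 (1.14 ± 0.11), Stat6 (0.81 ± 0.12) and Socs1 (0.80 ± 0.15). The camera adjusted p was 0.000918, and adjusted p = 0.210 with an estimated correlation. Interferon-stimulated genes went both ways, with 6 of 26 higher and 5 lower (the same counts adjusted over the list alone; camera adjusted p = 0.436).

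Macrophage, antigen presentation and complement genes were higher in hTNF joints. Of 28 macrophage and monocyte genes, 25 rose and none fell (25 and 0 adjusted over the list alone), with Itgam (3.02 ± 0.20) and Marco (2.81 ± 0.48) after Clec4e and Clec4d. The camera adjusted p was 4.95e-18, and adjusted p = 0.162 with an estimated correlation. Antigen presentation genes rose in 18 of 22 and fell in none, also adjusted over the list alone, including the class II genes H2-Eb1 (1.93 ± 0.14), H2-DMa (1.92 ± 0.18) and H2-Ab1 (1.81 ± 0.09) and the invariant chain Cd74 (1.43 ± 0.07). Of 16 complement genes, 11 rose and 2 fell (13 and 2 adjusted over the list alone), led by the receptor C3ar1 (2.47 ± 0.12), C1s1 (2.01 ± 0.15), Cfb (1.98 ± 0.29) and Cfp (1.86 ± 0.18). The camera adjusted p of the last 2 lists was 1.25e-09 and 1.67e-05, and the adjusted p = 0.168 for both with an estimated correlation. Neutrophil and granulocyte precursor genes rose in 4 of 19 (4 adjusted over the list alone), which were Fpr2 (3.43 ± 0.48), Mcemp1 (2.09 ± 0.25), Trem1 (1.5 ± 0.17) and Csf3r (0.96 ± 0.17). That list's call (camera adjusted p = 0.0369; adjusted p = 0.663 with an estimated correlation) ended and turned in direction without wild-type replicate 1, where the list was low (adjusted p = 0.580), and ended without hTNF replicate 3 (0.0594), without replicate 1 of the arrays labelled null (0.0559) and with Y-linked signal as a covariate (0.140). T and NK cell genes (5 higher and 1 lower of 15; camera adjusted p = 0.0823) and B and plasma cell genes (5 higher and 1 lower of 23; 0.747) were not called as lists; both counts were the same adjusted over the list alone. The T and NK cell list was called higher without wild-type replicate 2 (adjusted p = 0.00771) and hTNF replicate 1 (0.0374), and the B and plasma cell list lower without wild-type replicate 1 (0.00434). Proliferation genes rose in 16 of 28 (24 adjusted over the list alone; camera adjusted p = 1.97e-06, adjusted p = 0.464 with an estimated correlation). The wild-type arrays differed in this list, and the mitotic gene Birc5 moved from 1.57 ± 0.44 to 0.61 without wild-type replicate 1 (adjusted p = 0.0910). Its call also ended without hTNF replicate 2 (0.0532) and replicate 3 (0.0550).

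Genes of lipid mediators were higher as well. Of 17 prostaglandin and leukotriene pathway genes, 8 rose and 3 fell (9 and 4 adjusted over the list alone; camera adjusted p = 0.0103, adjusted p = 0.339 with an estimated correlation). The prostaglandin receptors Ptger2 (2.37 ± 0.21) and Ptger4 (1.67 ± 0.17), the leukotriene genes Alox5ap (1.89 ± 0.11) and Alox5 (1.53 ± 0.14) and the prostaglandin E synthase Ptges (0.89 ± 0.12) rose. Of 28 genes of sphingolipid metabolism and sphingosine 1-phosphate receptors, 14 rose and 1 fell (15 and 2 adjusted over the list alone; camera adjusted p = 0.00129, adjusted p = 0.333 with an estimated correlation). Beside Sphk1 these included the ceramide synthase Cers6 (1.36 ± 0.15), the glucosylceramide synthase Ugcg (1.36 ± 0.16) and Sgpl1 (1.19 ± 0.12), the lyase that degrades sphingosine 1-phosphate. Sphk2 (0.40 ± 0.14), S1pr1 (-0.15 ± 0.14) and S1pr3 (-0.24 ± 0.13) did not pass, with limma adjusted p of 0.0587, 0.460 and 0.177.

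Matrix-degrading and bone-resorbing genes rose and cartilage genes fell. Of 27 matrix proteases and inhibitors, 18 rose and 4 fell (19 and 5 adjusted over the list alone; camera adjusted p = 4.25e-06, adjusted p = 0.154 with an estimated correlation), among them Mmp3, Adam8 (3.55 ± 0.12) and the collagenase Mmp13 (2.64 ± 0.23). Osteoclast genes rose in 12 of 17 and fell in none (13 and 0 adjusted over the list alone; camera adjusted p = 1.31e-05, adjusted p = 0.247 with an estimated correlation), with the fusion gene Dcstamp (2.04 ± 0.18), the collagen-degrading Ctsk (1.64 ± 0.23), Mmp9 (1.95 ± 0.53) and Acp5 (1.61 ± 0.43). Without wild-type replicate 1, Mmp9 moved to 0.79 (adjusted p = 0.0776) and Acp5 to 0.70 (adjusted p = 0.0943), and without hTNF replicate 2 both calls ended (0.0563 and 0.0523). Osteoclast regulators split evenly, 6 of 14 higher and 6 lower, also adjusted over the list alone. Cd44 (2.00 ± 0.09) and Trem2 (1.78 ± 0.15) rose, and the Wnt antagonist Frzb (-1.89 ± 0.21) and the decoy receptor Tnfrsf11b (-1.06 ± 0.14) fell. Its ligand Tnfsf11 differed by 0.12 ± 0.17 (limma adjusted p = 0.658). The median of that list was -0.01 and its mean 0.17 (camera adjusted p = 0.436). Of 21 cartilage genes, 13 fell and 2 rose (15 and 2 adjusted over the list alone), with Cytl1 (-2.04 ± 0.24), Snorc (-1.71 ± 0.32) and Chad (-1.70 ± 0.12) among the falls. The camera adjusted p was 0.000277, and adjusted p = 0.234 with an estimated correlation. Osteoblast and osteocyte genes (3 higher and 5 lower of 16; camera adjusted p = 0.638) and tendon genes (3 higher and 5 lower of 12; 0.582) were not called as lists, with the same counts adjusted over the list alone. The osteocyte gene Mepe fell by 1.30 on the log2 scale and the tendon gene Angptl7 by 2.29. Synovial and connective tissue fibroblast genes rose in 11 of 24 and fell in 4, also adjusted over the list alone (camera adjusted p = 0.00314, adjusted p = 0.162 with an estimated correlation). Postn (2.16 ± 0.13), Pdpn (1.78 ± 0.09) and Thy1 (1.64 ± 0.15) were higher, and Clic5, a marker of the synovial lining, was lower (-1.96 ± 0.17).

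Muscle, fat, nerve and vessel genes were lower in hTNF joints. All 32 skeletal muscle genes had a negative sign and 30 fell (32 adjusted over the list alone), with Myh4, Ckmt2 (-2.15 ± 0.38), Mybpc2 (-2.05 ± 0.28) and Myh7 (-2.0 ± 0.30) in front. All 23 genes of mitochondrial oxidative phosphorylation fell, also adjusted over the list alone, led by the muscle forms Cox7a1 (-1.83 ± 0.35) and Cox6a2 (-1.81 ± 0.20). The camera adjusted p of these lists was 1.53e-11 and 9.44e-11, and the adjusted p = 0.3 and 0.293 with an estimated correlation. Adipocyte genes fell in 17 of 19, also adjusted over the list alone, with Cidec (-2.67 ± 0.26) and Plin4 (-2.44 ± 0.21) after Lep and Thrsp (camera adjusted p = 9.81e-10, adjusted p = 0.162 with an estimated correlation). Of 10 Schwann cell and nerve genes, 9 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.000633, adjusted p = 0.234 with an estimated correlation). Ncmap (-1.81 ± 0.19), S100b (-1.52 ± 0.15) and the brightest probe set of Mbp (-1.43 ± 0.20) fell. Another Mbp probe set was called in the opposite direction, and Egr2 rose (1.33 ± 0.22). Endothelial genes fell in 13 of 20 and rose in 1, also adjusted over the list alone (camera adjusted p = 0.0119, adjusted p = 0.515 with an estimated correlation). Tek (-1.13 ± 0.18) and Cldn5 (-0.79 ± 0.10) were lower and the inflammation-induced selectin Sele was higher (1.26 ± 0.29; its adjusted p was 0.0714 without wild-type replicate 2). The endothelial call ended without the 3 arrays with both Xist and Y-linked signal (adjusted p = 0.0729), an alternative chosen after seeing the data. Of 4 measured mast cell genes, Cpa3 (-1.14 ± 0.17), Kit (-1.04 ± 0.16) and Cma1 (-0.89 ± 0.13) fell. Skin genes (0 of 23 called, also adjusted over the list alone; camera adjusted p = 0.0814), erythroid genes (1 higher and 3 lower of 15; 0.149), megakaryocyte and platelet genes (1 higher and 1 lower of 10; 0.582; median -0.10 but mean 0.10) and immediate early and hypoxia genes (6 higher of 18; 0.0556) were not called as lists. Adjusted over the list alone, the last 3 had 1 higher and 3 lower, 1 higher and 0 lower, and 6 higher. Leaving out 1 array gave calls for skin without hTNF replicate 2 (adjusted p = 0.000140) and 3 (0.0483), erythroid without wild-type replicate 1 (0.0119), megakaryocyte and platelet without wild-type replicate 2 (0.0328), and immediate early and hypoxia genes without wild-type replicate 1 (0.00815) and hTNF replicate 2 (0.00642).

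**Figure D2:**
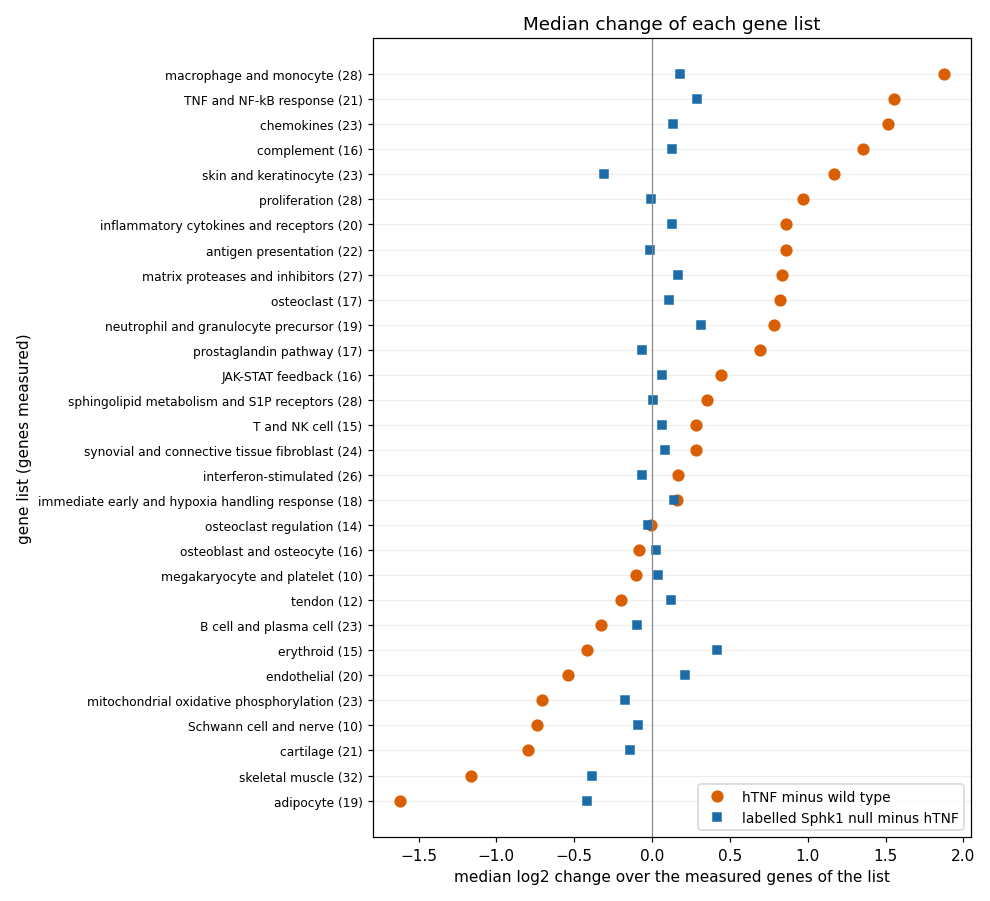
Median log2 change over the measured genes of each of 30 gene lists, for hTNF minus wild type (circles) and for the arrays labelled Sphk1 null minus hTNF (squares), with the number of measured genes in brackets. Medians run from -1.62 (adipocyte) to 1.87 (macrophage and monocyte) between hTNF and wild type and stay between -0.42 and 0.42 between the transgenic groups.

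Between the 2 transgenic groups few differences passed the test, and none of the called probe sets belongs to an inflammatory gene list. Limma called 2 of 24115 probe sets, Sphk1 itself and BC018473, which read 5.11 ± 0.06 log2 (SD, n = 3) in hTNF, 5.23 ± 0.11 (n = 2) in wild type and 7.61 ± 0.49 (n = 3) in the arrays labelled null. BC018473 was 2.51 ± 0.23 log2 (SE) higher, with a limma adjusted p of 0.0164. It was dim in hTNF, and with an offset of 32 before log2 the difference was 1.78 (limma adjusted p = 0.0360). At an unadjusted p under 0.05 there were 1835 probe sets (640 higher, 1195 lower), against 1206 by chance, and the groups did not overlap in 11.2% of probe sets, against 10% by chance. That count depended on single arrays: it was 789 without hTNF replicate 1, and 4890, 1156 and 1139 without replicates 1, 2 and 3 of the arrays labelled null. Both called genes were higher; with quantile normalization 6 probe sets were called, 5 higher and 1 lower. Leaving out 1 array at a time gave 0 calls in 7 of 8 cases and 3 without replicate 2 of the arrays labelled null. Over these fits the Sphk1 difference stayed between 1.41 and 1.60 with a limma adjusted p of 0.0328 to 0.190, and that of BC018473 between 2.36 and 2.79 with 0.00128 to 0.190. The median unadjusted 95% interval reached 0.30 log2 to either side, and changes of 2-fold and more also went uncalled after adjustment, among them those of Il1b, Igha and Myh4.

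Genes nearest to the threshold, none of which passed, were Apold1 (1.02 ± 0.12 log2; limma adjusted p = 0.125), an early-response gene of endothelium, St6galnac2 (1.09 ± 0.14; 0.125) and the protease Adamts1 (0.70 ± 0.10; 0.232) on the higher side. On the lower side they were Smim5 (-0.63 ± 0.12; 0.377), Mtarc1 (-0.62 ± 0.12; 0.406), the immunoglobulin A heavy chain Igha (-1.37 ± 0.29; 0.409), Mettl23 (-0.62 ± 0.13; 0.426) and Id1 (-0.45 ± 0.10; 0.453). Of the inflammatory genes, Il1b differed by 1.04 ± 0.23 (limma adjusted p = 0.438), Socs3 by 0.72 ± 0.16 (0.449), Tnf by 0.12 ± 0.12 (0.832), Ptges by -0.08 ± 0.11 (0.872) and Il17a by 0.12 ± 0.12 (0.828). No bone or matrix gene among those always reported passed, with Mmp3 at 0.16 ± 0.16, Mmp13 at 0.33 ± 0.20, Mmp9 at 0.24 ± 0.48, Acp5 at 0.24 ± 0.39, Ctsk at 0.11 ± 0.21. With Tnfsf11 at 0.46 ± 0.16 and Tnfrsf11b at -0.18 ± 0.12, their limma adjusted p ran from 0.611 to 0.924. The 95% intervals of Mmp9 (-0.83 to 1.31) and Acp5 (-0.63 to 1.11) leave room for changes over 2-fold. The sphingosine genes Sphk2 (0.09 ± 0.13), S1pr1 (0.48 ± 0.12) and S1pr3 (-0.14 ± 0.11) did not pass either.

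No member of any list except Sphk1 was called in this contrast, yet small shifts ran one way through many lists. Of 21 TNF and NF-kB response genes, 20 had a positive sign (median 0.29 log2; camera adjusted p = 4.03e-07), as had 23 of 28 macrophage genes (median 0.18; 3.45e-06), 21 of 27 matrix proteases and inhibitors (0.17; 5.74e-06) and 17 of 20 endothelial genes (0.21; 1.39e-06), with Sele at 1.05 ± 0.26. For these 4 lists the adjusted p = 0.373, 0.373, 0.248 and 0.373 with an estimated correlation. The largest positive medians were those of erythroid genes (0.42, 13 of 15 positive; camera adjusted p = 0.00113) and neutrophil and granulocyte precursor genes (0.32, 18 of 19 positive; 0.00388), with adjusted p = 0.421 and 0.556 with an estimated correlation. Without replicate 3 of the arrays labelled null both calls ended (0.255 and 0.513), and the neutrophil call also ended without hTNF replicate 2 (0.0515) and with Y-linked signal as a covariate (0.176). Inflammatory cytokines and receptors went both ways, with 13 of 20 positive and 7 negative. Adjusted over that list alone, 1 gene was higher (Il1b) and 1 lower (the interleukin 6 receptor gene Il6ra, -0.69 ± 0.18). That list was called higher (camera adjusted p = 0.00771), with an adjusted p = 0.373 with an estimated correlation, and its call ended without the 3 arrays with both Xist and Y-linked signal (0.107). Of 32 muscle genes, 30 had a negative sign (median -0.39; camera adjusted p = 5.06e-12), although Myh4 differed by 1.41 ± 0.32. So had 17 of 19 adipocyte genes (-0.42; 4.03e-07) and 22 of 23 oxidative phosphorylation genes (-0.18; 3.52e-06). For these 3 lists the adjusted p = 0.373, 0.373 and 0.471 with an estimated correlation. Adjusted over the list alone, the matrix protease list had 1 called gene, Adamts1, and the TNF and NF-kB, macrophage, endothelial, erythroid, neutrophil, muscle, adipocyte and oxidative phosphorylation lists had none. Cartilage genes were called lower (17 of 21 negative, median -0.14; camera adjusted p = 0.00833, adjusted p = 0.421 with an estimated correlation), but not without replicate 1 of the arrays labelled null (0.600), and the direction turned without the 3 arrays with both signals (0.884). Sphingolipid genes, among them Sphk1 itself, were called higher with 14 positive and 13 negative signs (camera adjusted p = 0.0386, adjusted p = 0.553 with an estimated correlation). The median of this list was 0.01 log2 and its mean 0.08, and the share of Sphk1 in the list's call was not tested. That call ended in 5 of 8 fits that left out 1 array: wild-type replicates 1 (0.0526) and 2 (0.0529), hTNF replicates 2 (0.114) and 3 (0.0519), and replicate 1 of the arrays labelled null (0.233). Camera called 20 of 30 lists at the preset correlation, 15 higher and 5 lower, none with an estimated correlation (adjusted p = 0.248 to 0.556 for the 20). Fry called 1, the synovial and connective tissue fibroblast list (fry adjusted p = 0.01; median 0.08; camera adjusted p = 0.248 with an estimated correlation), whose camera call ended without replicate 2 of the arrays labelled null (0.105). The Gapdh control signal, 3' minus 5' end, was 0.26 to 0.35 log2 on the arrays labelled null and 0.19 to 0.23 on the hTNF arrays. Median, mean and test disagreed in sign for osteoblast and osteocyte, proliferation, antigen presentation and osteoclast regulation genes, none of which was called.

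The transgene response was not reversed in the arrays labelled Sphk1 null. Over probe sets that rose with the transgene, these arrays lay 0.08 ± 0.09 log2 (mean and SD over 3 held-out hTNF arrays) above the held-out array, beside a median response of 0.85, and 0.01 without replicate 1 of the arrays labelled null. For probe sets that fell they lay -0.15 ± 0.06 from it, further from wild type, beside a response of -0.85. The median for fallen probe sets was -0.22 without replicate 1 of the arrays labelled null and -0.09 without replicate 2. Across probe sets, which are not independent replicates, the 2 contrasts correlated at 0.27. Simulated unchanged groups gave -0.45 (range -0.51 to -0.39) because both contrasts share the hTNF arrays. These groups also lack the transgene effect, and their noise was drawn separately for each probe set. Neither -0.45 nor its range is therefore a like reference for 0.27. The covariance, which is not divided by the spread of the transgene response, was 0.0366 against -0.0149 in the simulation.

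Joints labelled Sphk1 null differed from wild type much as hTNF joints did. The largest rises were again Clec4e (6.93 ± 0.23 log2), Cxcl3 (6.33 ± 0.26), Saa3 (6.23 ± 0.26) and Cxcl13 (5.92 ± 0.36), and the largest falls Lep (-3.75 ± 0.22), the muscle gene Myoz2 (-3.34 ± 0.30), Thrsp (-3.26 ± 0.25) and Nnat (-3.16 ± 0.42), with limma adjusted p of at most 0.000365. Sphk1 was higher by 2.85 ± 0.15, Il1b by 3.79 ± 0.25, Socs3 by 2.00 ± 0.18, Mmp3 by 4.93 ± 0.17, Mmp13 by 2.97 ± 0.23 and Ctsk by 1.75 ± 0.23. Sphk2 (0.49 ± 0.14; limma adjusted p = 0.0235), Tnfsf11 (0.58 ± 0.17; 0.0261) and S1pr3 (-0.39 ± 0.13; 0.0379) passed here and not in hTNF against wild type, but their difference between the transgenic groups did not pass. The Sphk2 call ended without wild-type replicate 1 (0.0792), wild-type replicate 2 (0.119) or replicate 3 of the arrays labelled null (0.0708). Tnfsf11 moved to 0.34 without wild-type replicate 1 (limma adjusted p = 0.236), and its call ended without replicate 1 (0.0504) or 3 (0.0774) of the arrays labelled null and with Y-linked signal as a covariate (0.0543). S1pr3 moved to -0.23 without wild-type replicate 2 (limma adjusted p = 0.289), and its call ended without hTNF replicate 3 (0.0594) or replicate 2 (0.0944) or 3 (0.0896) of the arrays labelled null and with Y-linked signal as a covariate (0.110). Other probe sets of Sphk2 and S1pr3 had the opposite sign. In all, 9395 probe sets were called (4513 higher, 4882 lower). Of the probe sets that rose in hTNF, 3553 also rose here, and of those that fell 3761 also fell, while none was called in opposite directions. Independent lists of these sizes would share 751 and 800, and simulated groups with no change shared 0.02. The first leaves out the shared arrays and the second leaves out all effects, so neither excess measures a shared effect. Both contrasts use the same 2 wild-type arrays, which are too few to split, so part of the excess may come from them. Camera called 21 lists, 16 higher and 5 lower, and none with an estimated correlation (adjusted p = 0.122 to 0.593 for the 21). All 21 TNF and NF-kB genes rose and all 32 muscle genes fell, and both counts held adjusted over the list alone. The actin control signal, 3' minus 5' end, was 0.53 to 0.74 log2 on the arrays labelled null and 0.37 and 0.45 in wild type. That of Gapdh was 0.26 to 0.35 and 0.12 and 0.25. Erythroid genes had a median of 0.17 and a mean of 0.05 but ranked lower by camera (adjusted p = 0.926).

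Genes beside Sphk1 on its chromosome were examined because both called genes lie there in the GRCm38.p6 gene order, and both this choice and the number of neighbours were made after the values were seen. Of the 10 measured genes on either side, 4 had an unadjusted limma p under 0.05 between the transgenic groups, all on the same side as BC018473: besides it, the sialyltransferases St6galnac2 (1.09 ± 0.14 log2) and St6galnac1 (0.53 ± 0.14; limma adjusted p = 0.554) and Mxra7 (-0.37 ± 0.10; 0.558). The others differed by -0.33 to 0.32. The window ends after 10 genes on either side, so it does not show whether genes further out also differed.

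**Figure D3:**
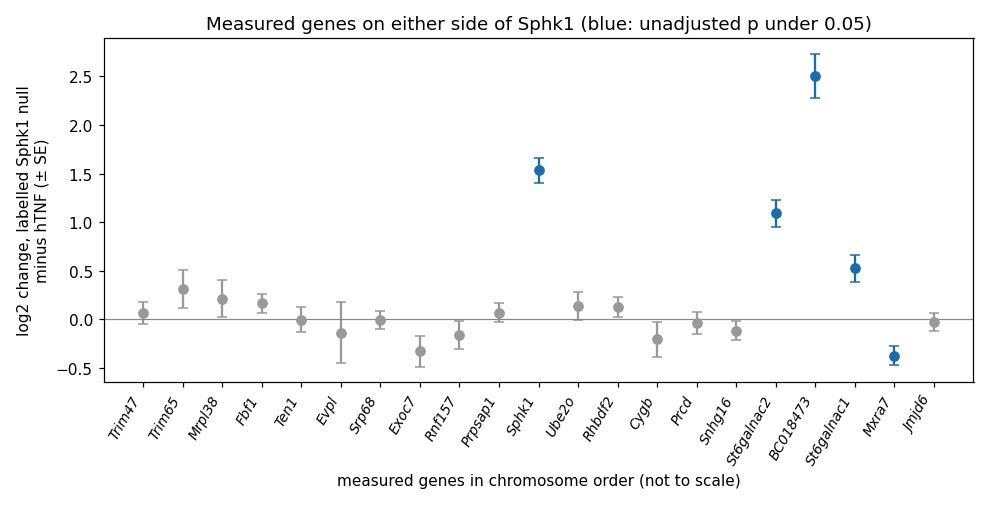
Log2 change between the arrays labelled Sphk1 null and the hTNF arrays, with standard errors, for Sphk1 and the 10 measured genes on either side of it in GRCm38.p6 gene order (not to scale). Sphk1 at 1.53, BC018473 at 2.51 and St6galnac2 at 1.09 stand above the rest, and only the first 2 of these passed the adjusted threshold.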

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

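All tests in this part were chosen only after the result they address was seen, except the count over other splits of the arrays; the quantile-normalized value had been seen before its expectation was written. The control probe sets, which no comparison uses, gave a signal at the 3' end above that at the 5' end, and the difference exceeded that of both wild-type arrays (0.37 and 0.45 log2 for actin, 0.12 and 0.25 for Gapdh) on several transgenic arrays. For actin it was 0.60, 0.47 and 0.57 on hTNF replicates 1, 2 and 3 and 0.53, 0.74 and 0.67 on the arrays labelled Sphk1 null, replicates 1, 2 and 3. For Gapdh it was 0.26, 0.32 and 0.35 on the arrays labelled null and 0.22, 0.19 and 0.23 on the hTNF arrays. The share of RNA quality in the changes of any of the 3 comparisons was not tested.

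Sphk1 and its neighbour BC018473 were called between the arrays labelled Sphk1 null and hTNF. Of 20 neighbours, 4 had an unadjusted limma p under 0.05, BC018473 included, and the others of these did not pass the adjusted threshold. A stronger transgene response was argued against as the whole cause for Sphk1. The lower 95% bound of the Sphk1 change (1.24 log2) exceeded the upper bound of its transgene response in that direction times a slope (0.32). The slope over all probe sets, with the simulated covariance of the shared arrays taken off, was 0.139. The slope used, 0.195, takes it off a second time, which makes the bound wider. BC018473 was at -0.12 log2 under the transgene and 2.51 between the transgenic groups. It and St6galnac2 (-0.66 and 1.09), Mxra7 (0.20 and -0.37) and St6galnac1 (0.12 and 0.53) also passed the bound, which cannot decide for them. They were picked by their p in this contrast, so their interval left out 0 by selection, and the bound allowed them at most 0.09. For BC018473 the lower 95% bound of the change was 1.99 log2. Opposite signs can also come from the hTNF arrays, which both contrasts share. This bound was set with all values known, after a first count over the neighbours (5 of 20 outside the central 95% of genes with a like response, 3 without BC018473 and St6galnac2, which had been seen before) had decided nothing. Altered or donor-strain DNA around Sphk1 may be a candidate explanation, but the window was set after neighbours had been seen, and 4 of 20 neighbours with an unadjusted limma p under 0.05 is a number that 4.02% of 11893 other windows of measured genes also reached, so it stays open, as does loss of Sphk1 function itself, untested. An exchange of the labels of the 2 transgenic groups also stays open, since hTNF lay further from wild type than the arrays labelled null for 2 of the 5 neighbours outside the central 95% (exact one-sided binomial p = 0.5).

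Probe sets that fell with the transgene were lower still in the arrays labelled Sphk1 null. Scaling between arrays was argued against as the whole cause, since the median stayed at -0.12 ± 0.05 log2 (SD over held-out arrays) with quantile normalization, and so was one hTNF array with a smaller response, since the highest of the 3 held-out medians was -0.0867. A smaller share of muscle and fat would raise macrophage and cartilage genes alike. The macrophage list mean was 11.27 log2 in hTNF and 11.44 in the arrays labelled null, and the cartilage list mean 8.73 and 8.52. The first minus the second was 0.37 log2 higher in the arrays labelled null, which goes against this explanation. The arrays overlapped (2.82 to 3.05 against 2.25 to 2.83), so it stays open. An effect of the Sphk1 genotype stays open too and was not tested apart from these.

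The arrays differed in Xist and Y-linked transcripts, and replicate 1 of the arrays labelled Sphk1 null carried both. RNA of male and female tissue on one array may be the source: Xist was at 27.5% of its level on the 3 arrays without Y-linked signal, which would put Y-linked genes 0.46 log2 below the male arrays, and they were 0.0667 ± 0.28 (SD over 3 genes) above, a gap of 0.53 that passes the bound of 0.5 by less than that spread. The clause on the spread was added after the value was seen, and without it the mixture would have been argued against, so it stays open only under that clause. Y-linked signal was present on 2 of 3 hTNF arrays and 1 of 3 arrays labelled null. Its presence was argued against as the whole cause of the 2 calls between the transgenic groups. Both, and 2 in all, were called with it as a covariate (Sphk1 1.64 ± 0.10 log2, limma adjusted p = 0.00142, and BC018473 2.58 ± 0.24, limma adjusted p = 0.0247). The covariate does not measure sex. It counts wild-type replicate 2 and hTNF replicate 1 with the male arrays, though their Xist was 13.09 and 13.05 log2. Another probe set of Y-linked Kdm5d read 4.24 and 4.27 on these 2 arrays, against 6.98 and 7.07 on the male arrays. Sphk1 read 8.65 log2 on hTNF replicate 2, a male array, and 8.63 and 8.28 on hTNF replicates 1 and 3, with high Xist. On the arrays labelled null, where only replicate 1 had Y-linked signal, it read 9.94 to 10.22. The gap between the groups exceeds the spread within each, which argues against uneven sex as the whole cause for Sphk1. BC018473 differed by 2.36 to 2.79 with any 1 array left out, but was dim in hTNF. Uneven sex of the arrays stays open for BC018473 and for the other differences.

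The 6 transgenic arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05; the real split gave 2 calls, the highest other split 0, and 1 split gave as many as the real one, which is the real one itself. At an unadjusted limma p under 0.05, another split gave 4444 probe sets against 1835 for the real split. It groups hTNF replicates 1 and 2 with replicate 1 of the arrays labelled null, which points to a structure of the arrays. This split is the one by presence of Y-linked signal. It is also the one by the sign of the second principal component (13.5% of the variance), where hTNF replicate 3 was at only -0.15. The source of this structure was not tested. With Y-linked signal as a covariate the real contrast had 1439 probe sets at this level.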

How the results depend on the processing

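The X and Y chromosome probe sets and the 3 arrays with both Xist and Y-linked signal were left out, and Y-linked signal was used as a covariate, as alternatives chosen after seeing the data. For hTNF against wild type, 4606 probe sets were called with 1 probe set per gene, where fewer were tested, and 4695 to 9313 when 1 array was left out; against wild type, the arrays labelled null gave 5487 with 1 probe set per gene. Between the transgenic groups the count was 1 with the stricter dim filter, which removed BC018473, 6 with quantile normalization, 1 with array weights (Sphk1 was lost, and estimating the weights stopped early with a convergence warning), 0 without the 3 arrays, 2 with Y-linked signal as a covariate and 0 to 3 without 1 array. Where wild type keeps 1 array, that array is assumed to vary like the other groups.

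With Y-linked signal as a covariate 21, 17 and 19 lists were called in the 3 contrasts. The number of lists called fell to 0 in all 3 contrasts with an estimated correlation, and between the transgenic groups to 1 with fry and 3 with fry's mixed test, neither of which compares a list with other genes. The Sphk1 difference between the transgenic groups was 1.41 to 1.60 log2 without 1 array. The dim second Sphk1 probe set gave 0.33, -0.11 and 0.22 for hTNF against wild type, between the transgenic groups, and for arrays labelled null against wild type. The fallen probe sets of the transgene response were at -0.22 to -0.09 without 1 array; risen ones were at 0.01 to 0.11. 5 list results reversed: without 1 array, the neutrophil and granulocyte precursor list of hTNF against wild type (adjusted p 2.08e-06 to 0.580 over these fits) and the skin list between the transgenic groups (5.45e-08 to 0.526); without the 3 arrays, between the transgenic groups, osteoblast and osteocyte (0.0260), cartilage (0.884) and skin (0.00379). Of 1530 list values, 137 lost and 37 gained the call, and of 4800 named gene values, 110 lost and 9 gained it; 40 and 18 uncalled values changed sign. Except where said, the cause was not tested.

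Titles number the arrays alike, but only 5 of 8 arrays correlated best, as deviations from their group, with one of their own number (r of same-numbered arrays from -0.17 to 0.27), so the numbers do not pair the arrays. With the replicate number as a block, 6515 probe sets were called for hTNF against wild type, 2 between the transgenic groups and 7770 for the arrays labelled null against wild type. Dim probe sets limit what can be seen: Il6 never exceeded 7.43 log2 and Ptgs2 5.81.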

Other observations

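The description of these levels was chosen only after they were seen. Malat1, a nuclear long noncoding RNA, was lower on each array labelled Sphk1 null than on any other array. It read 10.98, 11.02 and 9.25 log2 on the hTNF arrays, 8.63, 6.87 and 7.70 on the arrays labelled Sphk1 null, and 8.86 and 9.60 in wild type. The 15 erythroid genes averaged 8.85 on replicate 3 of the arrays labelled null and 7.74 and 7.96 on replicates 1 and 2, against 7.58 to 7.96 on the hTNF arrays.

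Myh4, the fast myosin heavy chain, read 13.88 and 14.30 in wild type, fell to 10.48 to 11.11 in hTNF and read 11.44 to 12.90 in the arrays labelled null, a difference between the transgenic groups that did not pass (limma adjusted p = 0.453).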
